A study of Mus musculus with 10 samples.

How the data were processed

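Skin cells of CD1 mouse embryos were profiled by 10x Genomics single-cell RNA sequencing in 10 libraries. Per the labels, 3 embryos were pooled per library, skin was treated with trypsin for 20 min at 37 °C, and all live cells were sorted. The libraries form 5 littermate pairs of control and mutant: K14Cre with floxed β-catenin at E13.5 and E14.5, K14Cre with floxed Shh at E14.5 and E15.5, and Axin2CreER with Rosa-LSL-SmoM2YFP at E14.5 after tamoxifen (50 µg/g) at E11.5. Each group has 1 library, so pairs were compared without a test between libraries and cells were not used as replicates.

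The deposited matrices hold UMI counts per gene and barcode, without normalization. The submitters' processing notes name Cell Ranger 3.0, Seurat 3 and genome build mm10. Per the file headers, the matrices of the β-catenin and Shh lines came from Cell Ranger 3.1.0 and those of the SmoM2 pair from Cell Ranger 5.0.1. The references differed: 31053 features in the β-catenin line and the later Shh pair, 31056 in the Shh pair at E14.5, which adds GFP, tdTomato and Malat1, and 32286 in the SmoM2 pair, which adds eYFP. The 30406 genes shared by all libraries held 99.6% to 99.9% of the UMIs and were used throughout. The added entries were read separately. Libraries held 115993384 to 166882626 UMIs, and the annotation version is not stated. Counting intervals follow from the counts summed over a compartment or, for shares, from the number of cells.

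Cells with at least 1000 genes and at most 10.0% mitochondrial UMIs were kept, which was 58.6% to 88.4% of barcodes. The 2000 variable genes left out the fixed lists of Wnt, Hedgehog, FGF, BMP, Notch, placode, condensate, cell cycle, immediate early and erythroid genes. Genes of the other fixed lists, such as Crabp1, Krt1 and Krt10, were not left out. Principal components (30) of the variable genes gave a graph of 20 neighbours. Leiden clustering of it gave 7 broad and 40 fine clusters (resolution 0.02 and 1.0). The broad resolution was chosen after several had been inspected. Doublets were called per library as the cells with the most simulated doublets among 50 neighbours, at 0.8% per 1000 cells (5.24% to 7.96% of cells), and 8 fine clusters with mostly called doublets were left out. Broad clusters were named from a marker table fixed before the data were examined, by the class with the most markers among their top 10 genes. A fine cluster took the name of the broad cluster that held most of its cells, unless at least 2 of its top 10 genes were markers of another class and outnumbered those of the first. Outside epithelium and fibroblasts it also needed 2 markers of its own class. Some fine clusters of fibroblasts and epithelium therefore had no marker among their top 10 genes. A first naming by z-scores was dropped before any list was compared. Genes of the condensate and placode lists counted as markers of fibroblasts and epithelium. Fine clusters numbered 13 for dermal fibroblasts and 9 for epithelium, and 2 clusters (1027 cells), one of them rich in haemoglobin, were left unnamed.

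Counts were summed per library over epithelium (1271 to 3192 cells) and dermal fibroblasts (3418 to 5829 cells) and scaled to CPM. Log2 ratios add 1 CPM to each side. A list's value is the median over members with at least 5 CPM in either library, for 22 lists fixed before the data were examined. Its interval is the 2.5th to 97.5th percentile of 1000 Poisson redraws of the counts, and its percentile is taken among 10000 random lists of the same size, matched within 100 ranks of expression. CPM values have exact Poisson intervals and shares exact (Clopper-Pearson) binomial intervals, all at 95% and for counting error only. A share of 0 is given with the limit of 3 counts over the cells counted. A fold against 0 UMIs is a lower bound against a floor of 3 counts over the compartment. The condensate share counts fibroblasts with at least 4 of 14 genes after each cell was thinned to 3000 UMIs, and shallower cells were left out.

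Genes were named by a rule fixed before the data were examined. In each compartment and line, genes with at least 20.0 CPM in a library of each pair were ranked by the smaller log2 ratio of both stages (same sign), or by the single ratio in the SmoM2 pair. The value had to exceed the largest difference between any 2 of the 3 control libraries at E14.5, and the 6 highest and 6 lowest qualified, as they did for the steps between control stages in fibroblasts. Sex-linked transcripts, mitochondrial and haemoglobin genes and models without a gene name were left out. List members and Ctnnb1, Shh and Smo could be named besides.

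The log2 ratios, list percentiles and counting intervals were tested on simulated counts made from the fibroblasts of the Shh pair at E14.5, in which 200 of 9542 genes were changed. Clustering, naming and doublet calling were not simulated. True log2 ratios of -2, -1, 1 and 2 gave medians of -1.87, -0.93, 0.96 and 1.96. Of 200 unchanged lists, 6% fell outside the 2.5th to 97.5th percentile. These lists were drawn at random like those they were ranked among, so this value was largely fixed in advance. Neither differences between libraries nor shared regulation of list members was simulated, so it does not calibrate the percentiles of real lists. Exact Poisson intervals held the true mean for 95.7% of genes. The counting intervals of list medians held the true median for 99.5% of the 200 unchanged lists. For these lists they were thus wider than their nominal level. In simulated cells of 6000 and 15000 UMIs the thinned share was 35.0% and 35.1%, while the unthinned share was 84.6% and 99.98%.

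Alternatives fixed before the data were examined were a pseudocount of 5 CPM, no floor, called doublets kept, a stricter cell filter (2000 genes, 5.0% mitochondrial UMIs), equal weight per cell, scaling by the median of ratios, clusters at a resolution of 2.0, thinning to 2000 UMIs, and at least 3 or 5 condensate genes. Fibroblast clusters with Crabp1 at or above 2477 CPM and fibroblasts without the cluster that had Scx and Tnmd among its top 10 genes were added as alternatives after the data had been seen. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.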

Results

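The data are 10x Genomics single-cell RNA counts from the skin of CD1 mouse embryos. They comprise 10 libraries, each from 3 pooled embryos and all sorted live cells, arranged as 5 pairs of a control and a mutant library from littermates. In 2 pairs (E13.5 and E14.5) the K14Cre driver, active in epidermal keratinocytes, was combined with a floxed β-catenin gene (Ctnnb1). In another 2 (E14.5 and E15.5) it was combined with floxed Shh, the gene of the secreted Sonic hedgehog signal. The last pair (E14.5) carried Axin2CreER, a tamoxifen-dependent driver active in Wnt-responding cells, and SmoM2YFP, an active form of the Hedgehog transducer Smoothened fused to YFP, with tamoxifen given at E11.5. Each group had 1 library, so no difference between groups has a replicate check, and every interval given covers counting error alone. The libraries held 115993384 to 166882626 UMIs in 9101 to 11834 barcodes, and 80906 cells passed the filters, with a median of 10986 to 17588 UMIs per cell. Counts were summed over the cells of a compartment and scaled by the compartment total (CPM), and log2 ratios are mutant over control with 1 CPM added to each side.

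Epithelium and dermal fibroblasts were the 2 most abundant cell types in each library, and the epithelial share was lower in 4 of the 5 mutant libraries and differed by less than counting error in the other, that of Shh at E14.5. In the β-catenin line, epithelium made up 21.9% of 7837 control cells and 16.6% of 8755 mutant cells at E13.5, then 37.5% of 6890 and 20.3% of 7614 at E14.5. Dermal fibroblasts were 49.6% of control and 63.4% of mutant cells at E14.5. In the Shh line the epithelial shares were 35.0% of 8730 control and 34.9% of 9149 mutant cells at E14.5, and 30.8% of 6616 and 25.3% of 6206 at E15.5. In the SmoM2 pair they were 28.5% of 7219 and 19.5% of 6510. The shares are of sorted live cells without called doublets, so a lower share of 1 type raises the others.

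The first question was what epidermal β-catenin loss changed in the epithelium. At E13.5 the fixed list of Wnt target genes had a median log2 ratio of -1.57 (-1.70 to -1.38), and the list of placode genes, which mark the epithelial buds that begin hair follicles, had one of -0.92 (-1.03 to -0.82). At E14.5 the medians were -1.13 (-1.27 to -0.99) and -2.88 (-3.01 to -2.77). All 4 values lay below those of 10000 random gene lists matched on expression (percentile 0). The cells also lay in different clusters at E14.5: 1 led by Dkk4, Krt17 and Kremen2 held 673 of 2586 control and 30 of 1547 mutant epithelial cells, 1 led by Dkk4, Krt17 and Ltb held 230 and 10, and 1 made up mostly of E13.5 cells held 10 and 385. Dkk4, a secreted Wnt inhibitor of placodes, was at 62.3 CPM in control and 14.9 in mutant epithelium at E13.5. At E14.5 it had 3117 UMIs against 1 UMI, a ratio of 1795-fold (322 to 70927).

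The Wnt targets that differed included Lef1, the DNA-binding partner of β-catenin, at 209 and 62.3 CPM at E13.5 and at 137 and 47.7 at E14.5. Axin2, a feedback inhibitor of the pathway, was at 28.1 and 8.75 CPM, then at 19.3 and 8.11. Bambi, a decoy receptor for TGF-β ligands, was the exception in this list, with log2 ratios of 2.18 and 1.10. Among the placode genes, Edar, the ectodysplasin receptor, was at 8.71 and 1.67 CPM at E13.5 and at 9.22 and 0.320 at E14.5. Fgf20, a signal from placode to dermis, was at 9.88 and 0.498 CPM at E14.5, while Wnt10a, a Wnt ligand, was higher in the mutant library (0.64). Ctnnb1 itself was at 749 CPM (740 to 757) in control and 613 (603 to 622) in mutant epithelium at E13.5, and at 597 (590 to 604) and 458 (450 to 466) at E14.5. The labels do not name the deleted exons, and 3′ tag counts from outside a deleted part check nothing about the deletion.

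Immediate early and heat shock genes, which respond to tissue handling, were higher in the mutant epithelium at E13.5 (0.86, percentile 100), among them Fosb (2.20), Egr1 (1.95) and Fos (1.44), and erythroid RNA was at -0.71. Other signalling genes in this epithelium differed between the stages. The FGF response list was at 0.30 at E13.5 and at -1.07 at E14.5, where Etv4 and Dusp6, a transcription factor and a phosphatase induced by FGF, were at -3.24 and -3.36. The Shh transcript was at 0.214 and 0.156 CPM at E13.5. At E14.5 Shh was at 6.50 CPM (5.80 to 7.25) in control and had 0 UMIs in mutant epithelium, at least 60.9-fold lower. The Hedgehog target list had a median of -2.004 at E14.5. The genes with the largest higher values at both stages were Unc13c, a synaptic vesicle protein (4.15 and 3.57), Rspo3, a secreted Wnt enhancer (3.94 and 3.31), Lrrc7, a synaptic scaffold (3.28 and 3.83), and Ntm, a neural adhesion protein (2.95 and 3.93). The largest lower values at both stages were those of Bmp2, a BMP ligand of placodes (-2.44 and -2.84), Dkk4 and Cadm1, an adhesion protein (-1.85 and -3.45).

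Genes below 5 CPM were left out of the list medians. With all members counted, the E13.5 medians were -0.26 for Wnt targets and -0.51 for placode genes. With 5 CPM added to each side the E14.5 placode median was -1.43. With a stricter cell filter the E14.5 Wnt target median was -0.72, from 970 of 2586 control and 393 of 1547 mutant cells. With Shh at its bound, a change that could only lower it, the E14.5 placode median was -2.91.

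The next question was whether the dermis differed when β-catenin was lost from the epidermis. At E13.5 dermal fibroblasts hardly differed in the chosen lists: Wnt targets had a median of -0.05 (-0.08 to -0.00) and dermal condensate genes, which mark the fibroblast clusters under placodes, one of 0.07 (0.01 to 0.10). The sign of the Wnt value turned under a stricter cell filter (0.0299) and in the clusters with high Crabp1 (0.0446), a retinoic acid binding protein of the upper dermis; it also turned without the fibroblast cluster led by the tendon genes Scx and Tnmd (0.00880), and both subsets were chosen after the data had been seen. At E14.5 Wnt targets were at -0.09 (-0.17 to -0.05), condensate genes at -0.85 (-0.92 to -0.77) and Hedgehog targets at -2.42 (-2.52 to -2.29), the last 2 at percentile 0. Ptch1, the Hedgehog receptor and a target of its own pathway, was at 46.7 CPM (44.8 to 48.7) in control and 7.30 (6.65 to 7.98) in mutant fibroblasts at E14.5, against 4.81 and 4.94 at E13.5.

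The condensate genes with the lowest values at E14.5 were Foxd1, a forkhead transcription factor (30.98 CPM in control and 0.964 in mutant fibroblasts), Sox2, a transcription factor (12.1 and 0.352), and Sox18, a related factor (15.2 and 0.566). Rspo3 and Inhba, an activin subunit, were higher (0.80 and 0.40). Gli1, a transcription factor and Hedgehog target, was at 17.6 and 2.52 CPM. Dkk1, a secreted Wnt inhibitor, was at 44.8 and 7.75 CPM, which made it the Wnt target with the lowest ratio (-2.39), while Notum, another secreted inhibitor, was higher (0.63). The BMP response list was at -0.84 with 4 of 4 genes lower, Id1, a BMP-induced inhibitor of differentiation, at 241 and 81.1 CPM. The extracellular matrix list was at 0.22. Keratinocyte transcripts in fibroblasts, read as free RNA, were at -0.89, beside the smaller epithelial share of that library. Of genes with the same direction at both stages, C1qtnf3, a secreted protein of connective tissue, had the largest higher value (1.24 at E13.5). It leads the cluster with Scx and Tnmd, which had no fibroblast marker among its 10 leading genes, was counted as fibroblast through its broad cluster and held 469 of 4530 control and 1001 of 5829 mutant fibroblasts at E13.5, and 2 of 3418 and 38 of 4831 at E14.5. Id3, a relative of Id1, had the largest lower value (-0.35 at E13.5 and -1.06 at E14.5).

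Taking the mean of per-cell values instead of summed counts gave a condensate median of -1.34 at E14.5, and the clusters with high Crabp1 gave -2.18.

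Shh loss was asked about next, in the epithelium that was to lose it and in the dermis. In dermal fibroblasts Hedgehog targets had a median of -2.30 (-2.46 to -2.14) at E14.5 and -2.35 (-2.50 to -2.22) at E15.5, with 4 of 4 genes lower at both stages and percentile 0. Dermal condensate genes had medians of -0.60 (-0.71 to -0.43) and -1.05 (-1.14 to -0.95). In the epithelium of the libraries labelled Shh knockout, placode genes were higher, at 0.84 (0.74 to 0.97) and 1.11 (1.02 to 1.21). Wnt targets there were at 0.55 (0.41 to 0.62) and 0.93, and Hedgehog targets at -2.08 and -2.63. The placode list includes Shh itself, and Dkk4 belongs to both the placode and the Wnt target list, so these medians are not independent.

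The Shh transcript was at 3.53 CPM (2.99 to 4.14) in control epithelium and 11.6 (10.6 to 12.6) in that of the library labelled Shh knockout at E14.5. At E15.5 it was at 11.6 and 57.5 CPM (55.0 to 60.1). Tag counts from the 3′ end say nothing about whether the floxed part was removed, and the labels do not name that part. In fibroblasts, Ptch1 was at 30.4 CPM (28.7 to 32.2) in control and 4.80 (4.16 to 5.52) at E14.5, and at 63.6 (61.4 to 65.8) and 6.88 (6.22 to 7.58) at E15.5. Gli1 was at 15.6 and 1.25 CPM, then at 18.4 and 2.71. Hhip, a Hedgehog-binding surface protein, was at 7.04 and 2.32 CPM, then at 7.88 and 1.07. In epithelium, Ptch1 was at 19.5 and 3.85 CPM, then at 49.2 and 5.68.

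Among condensate genes of these fibroblasts, Foxd1 had 3 UMIs in the library labelled Shh knockout at E14.5, a ratio of 132-fold (44.7 to 641), and was at 40.0 and 2.93 CPM at E15.5. Sox2 was at 5.52 and 0.145 CPM, then at 9.74 and 0.494. Sox18 was at 32.8 and 0.204 CPM at E15.5. Cdkn1a, an inhibitor of the cell cycle, was lower at both stages (-1.61 and -1.05), as was Cbr3, a carbonyl reductase (-1.95 and -1.96). Inhba was higher at E15.5 (0.35), as was Bmp4, a BMP ligand (0.22). The FGF response list was higher at both stages (0.30 and 0.55, with 8 of 8 genes), and at E15.5 the BMP response list was at 0.49 with Msx1, a homeobox target of BMP, at 0.154 and 8.32 CPM. Of the genes with higher values at both stages, Casz1, a zinc finger factor, was at 0.57 and 1.62 and Irx3, a homeobox factor, at 0.45 and 1.21. Wnt targets in fibroblasts were at 0.09 and 0.13.

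In epithelium, Dkk4 was at 86.0 and 209.8 CPM at E14.5 and at 55.3 and 186 at E15.5. Bmp2 was higher at both stages (1.25 and 1.35), and so were Edar (7.25 and 12.1 CPM, then 9.99 and 16.9) and Fgf20 (9.59 and 20.5 CPM, then 12.8 and 33.6). Lhx2, a homeobox factor of follicle buds, was an exception (-0.95 at E15.5). Sostdc1, a secreted inhibitor of BMP and Wnt signals, was lower (-1.66 and -1.06), and so was Pou3f1, a POU factor of the epidermis (-0.70 and -2.38). The epidermal differentiation list differed by stage, at 0.38 with 9 of 9 genes higher at E14.5 and at -1.20 with 9 of 9 lower at E15.5. Krt10, a keratin of suprabasal cells, was at 282 and 350 CPM, then at 1916 and 590. A cluster with Asprv1, a protease of the upper epidermis, Krt1 and Krt10 among its leading genes held 115 of 3059 control epithelial cells and 206 of 3192 of the library labelled Shh knockout at E14.5 (3.76% and 6.45%). A cluster led by Ly6d, a surface protein of the suprabasal layer, Krt1 and Krt10 held 418 of 2036 control epithelial cells and 117 of 1572 of the library labelled Shh knockout at E15.5.

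With 5 CPM added to each side, the Hedgehog target medians in fibroblasts were -1.36 at E14.5 and -1.39 at E15.5. The E14.5 condensate median was -1.66 in the clusters with high Crabp1.

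The SmoM2 pair asked what active Smoothened in Wnt-responding cells changed. In dermal fibroblasts Hedgehog targets had a median of 2.71 (2.63 to 2.79) and condensate genes one of 0.99 (0.84 to 1.11), both at percentile 100, while Wnt ligands were at -1.61 with 5 of 5 genes lower. In the epithelium placode genes had a median of -3.17 (-3.33 to -3.01) with 8 of 8 genes lower, at percentile 0. The eYFP tag was detected in 43.6% (42.1 to 45.2) of 4022 mutant fibroblasts and 0.184% of control fibroblasts. It was detected in 0.787% (0.378 to 1.44) of 1271 mutant and 0.534% of control epithelial cells. Most mutant fibroblasts formed 1 cluster that the control library hardly shared, with 3304 of 4022 cells against 12 of 3805.

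Ptch1 in these fibroblasts was at 40.1 CPM (38.2 to 42.1) in control and 337 (333 to 342) in the mutant library, Hhip at 12.1 and 256, and Gli1 at 19.9 and 47.2. Smo, the gene that SmoM2 derives from, was at 77.5 and 88.6 CPM. The condensate genes did not move together: Foxd1 was at 28.1 and 272 CPM and Sox18 at 24.0 and 303, whereas Bmp4 was lower (-2.74) and Sox2 was at 15.8 and 10.1. Rspo3, Inhba and Prdm1, a transcriptional repressor, were also lower (-0.52, -1.15 and -0.73). The largest higher values were those of Pdlim3, a protein of the actin cytoskeleton (1.51 and 186 CPM), Fgf5, a growth factor (0 UMIs in control and 56.6 CPM, at least 788-fold higher), Hhip and Foxd2, a forkhead factor (4.23). The largest lower values were those of Calb1, a calcium-binding protein (-3.60), Casz1 (-3.57), Rspo1, a secreted Wnt enhancer (-3.18), and Irx3 (-3.17). Crabp1 was at 4152 and 854 CPM. The ligands Wnt4, Wnt6 and Wnt11 were at 163 and 52.5, 23.2 and 5.92, and 75.9 and 21.9 CPM. The extracellular matrix list was at -0.61 with 14 of 16 genes lower, among them Eln, elastin (98.2 and 25.8 CPM). Wnt targets were at -0.50, with Dkk1 the other way (72.2 and 265 CPM). The cell cycle list was at 0.07.

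In the SmoM2 epithelium, Dkk4 was at 117 CPM in control with 0 UMIs in the mutant library, at least 782-fold lower, and Shh had 1 UMI, a ratio of 229-fold (40.8 to 9061). Fgf20 was at 24.4 and 0.449 CPM, Edar at 11.2 and 2.49, and Ltb, a TNF family ligand of placodes, at -4.77. The 2 clusters led by placode genes held 441 of 2061 control and 2 of 1271 mutant epithelial cells. In the other clusters the placode median was -1.43 (-1.72 to -1.12), over the 5 genes that reached the floor there. Wnt targets were at -0.44 with 8 of 9 genes lower, Axin2 being the exception (0.31). Hedgehog targets were at -2.32. The differentiation list was at 0.64 with 8 of 8 genes higher, and Krt10 was at 340 and 755 CPM. Stfa3, a protease inhibitor, Ndufa4l2, a mitochondrial protein induced by hypoxia, and Cdh4, a cadherin, had the largest higher values (3.85, 3.72 and 3.09). Ctnnb1 was at 836 and 440 CPM.

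In the fibroblast clusters with high Crabp1, which leave out the cluster of mostly mutant cells, Hedgehog targets were at -1.07 and condensate genes at -1.30. With Dkk4 at its bound the SmoM2 placode median stayed at -3.17, which was fixed in advance, since Dkk4 was already the lowest member and moved lower.

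**Figure D1:**
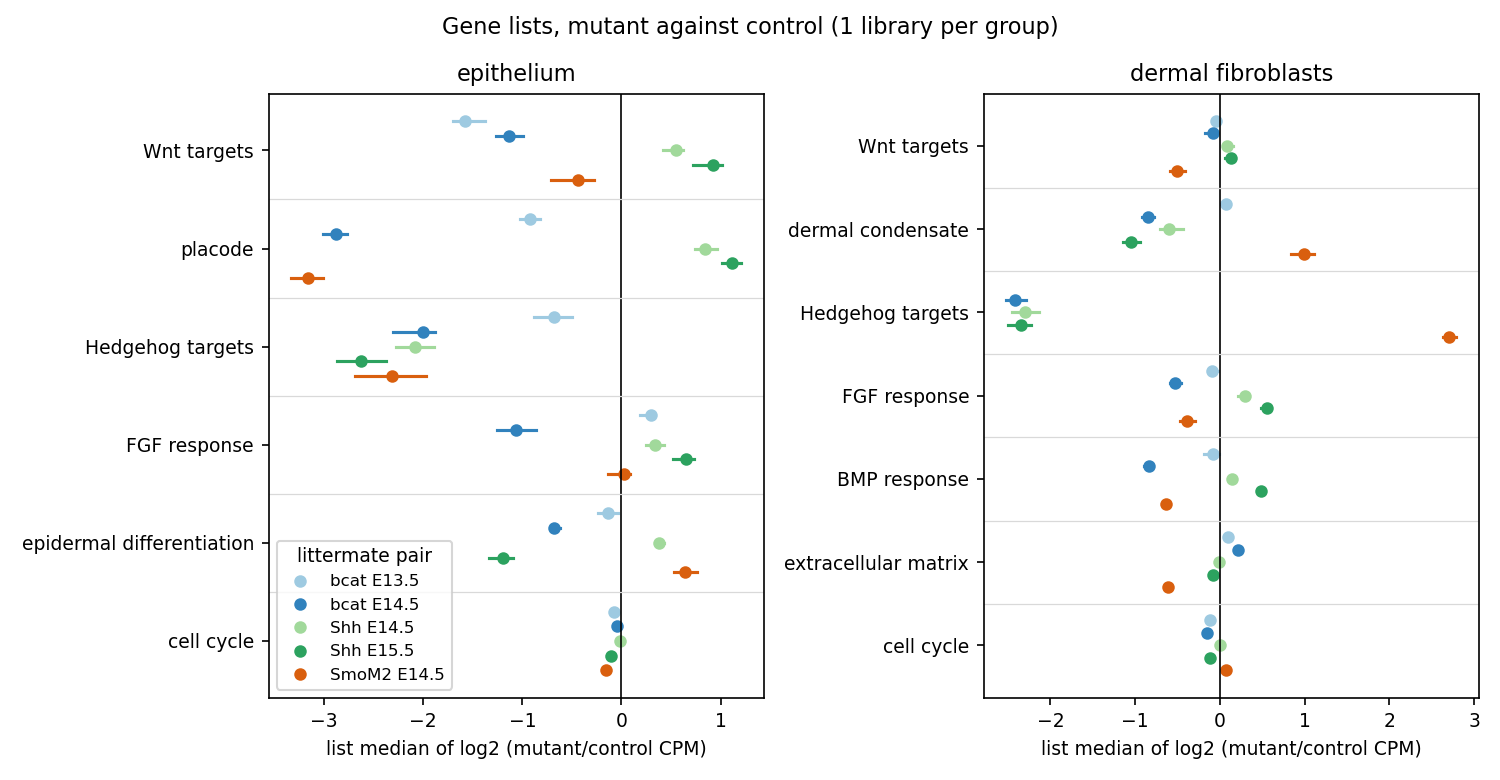
Median log2 ratio of gene lists, mutant over control, for the 5 littermate pairs in epithelium (left) and dermal fibroblasts (right). Lines give the nominal 95% counting interval, and each group had 1 library. Placode genes in epithelium ran from -3.17 in the SmoM2 pair to 1.11 in the Shh pair at E15.5, and Hedgehog targets in fibroblasts from -2.42 to 2.71.

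**Figure D2:**
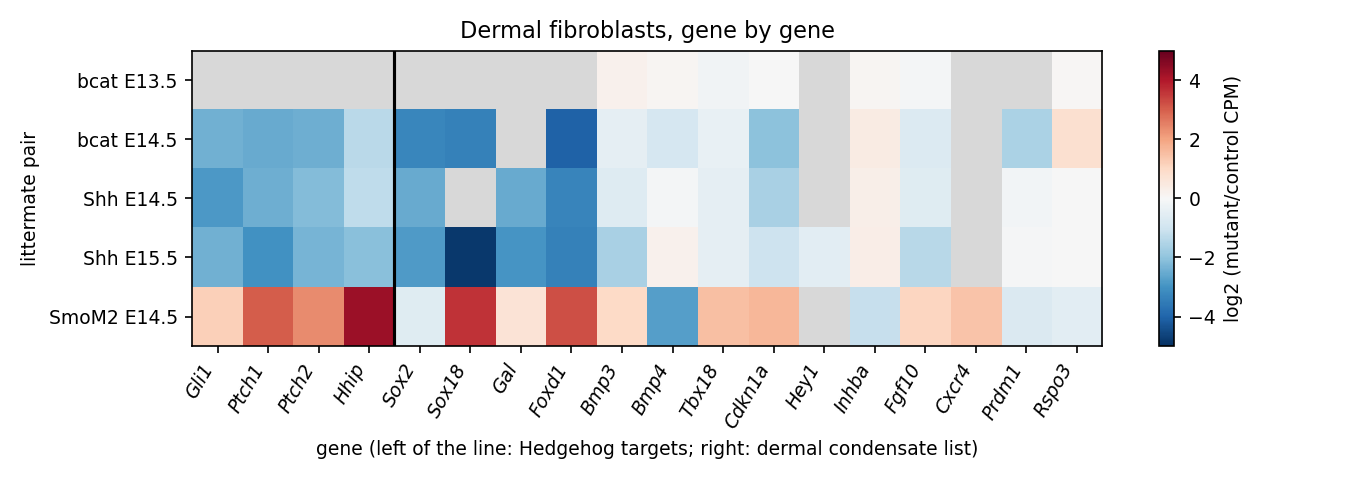
Log2 ratio of each Hedgehog target and each dermal condensate gene in dermal fibroblasts, by littermate pair, with grey for genes below 5 CPM in both libraries. Ptch1 was lower in both Shh pairs (-2.44 and -3.04), and in the SmoM2 pair Sox18 was higher (3.60) while Bmp4 was lower (-2.74).

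The share of fibroblasts with a condensate profile was counted after thinning each cell to 3000 UMIs, as those with at least 4 of the 14 condensate genes, Sox2, Foxd1 and Bmp4 among them. Between 12 and 66 fibroblasts per library were too shallow and were left out. It was 0.222% (0.106 to 0.408) in control and 0.190% (0.0949 to 0.340) in mutant fibroblasts of the β-catenin line at E13.5, a difference not detectable at this depth. At E14.5 it was 4.29% (3.63 to 5.02) and 0.375% (0.223 to 0.592). In the Shh line it was 2.12% (1.70 to 2.60) in control and 0.369% (0.215 to 0.590) in the library labelled Shh knockout at E14.5, then 4.91% (4.21 to 5.68) and 0.356% (0.189 to 0.607) at E15.5. In the SmoM2 pair it was 3.96% (3.36 to 4.63) in control and 15.9% (14.7 to 17.0) in mutant fibroblasts. Of the listed genes, Foxd1 (28.1 and 272 CPM) and Sox18 (24.0 and 303) were higher in these mutant fibroblasts, while Sox2, Bmp4, Rspo3, Inhba and Prdm1 were lower. Which genes made up the count in each cell was not examined, so this share is not one of cells with Sox2 and Bmp4. Epithelium, a type without condensate cells, had 0 such cells in each library, which allows a share of up to 0.0941% to 0.237% (3 cells of those counted). Among the other types without them, vascular endothelium had 1 such cell of 61 in the β-catenin control library at E14.5 (1.64%, with 0.0415 to 8.80), 1 of 56 in the library labelled Shh knockout at E14.5 and 1 of 80 in the SmoM2 mutant library. Skeletal muscle had 1 of 443 in the latter (0.226%, with 0.00571 to 1.25) and no such cell in the other libraries. Shares as low as those of the mutant β-catenin and Shh fibroblasts were not told apart from those of endothelium and muscle, which had fewer cells than epithelium. The share of the library labelled Shh knockout at E14.5 did lie above that of its epithelium, with 0 of 3187 cells (0 to 0.116%). In the other β-catenin and Shh mutant libraries the intervals of fibroblasts and epithelium overlapped.

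A cluster marked by Sox2, Foxd1, Bmp4, Gal, Cdkn1a and Sox18 gave another count of condensate cells. It held 149 cells of the β-catenin control library at E14.5 and 3 of the mutant, 72 and 1 in the Shh line at E14.5, and 223 and 1 at E15.5. In the SmoM2 pair it held 148 control and 5 mutant cells, so the higher share of the mutant library lay outside this cluster. Before thinning, the shares with at least 4 of these genes were 8.01% and 6.38%, 14.04% and 9.65%, 7.64% and 4.51%, 15.3% and 10.8%, and 14.03% and 57.2%, in the same order of pairs. In the SmoM2 mutant 373 of the 632 counted cells had exactly 4 genes and another 640 cells had 3. The differences, in percentage points, depended on the settings: the SmoM2 difference of 11.9 was 5.55 at 2000 UMIs per cell, 5.87 with a stricter cell filter, 24.2 with at least 3 genes and 3.85 with at least 5. It was -4.02 in the clusters with high Crabp1. The β-catenin difference of -3.91 at E14.5 was -2.58 under the stricter filter, that of -0.0317 at E13.5 was -0.510 with at least 3 genes and 0.0418 at 2000 UMIs, 0.0124 with at least 5 genes and 0.0354 without the cluster led by Scx and Tnmd, and the Shh difference of -1.75 at E14.5 was -2.85 in the clusters with high Crabp1.

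**Figure D3:**
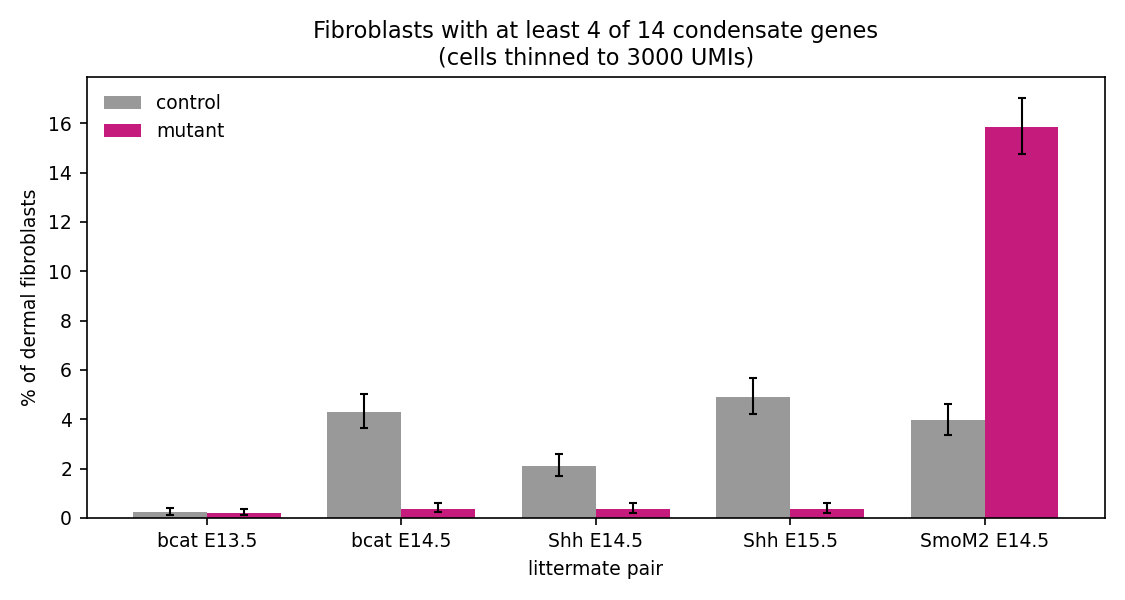
Percent of dermal fibroblasts with at least 4 of the 14 condensate genes after thinning to 3000 UMIs, for control and mutant libraries of the 5 littermate pairs, with exact 95% binomial intervals. The share was 15.9% in the SmoM2 mutant and at most 0.375% in the mutant libraries of the other lines.

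The last question was how control skin differed by stage. In fibroblasts of the β-catenin line, Hedgehog targets were 2.39 higher on the log2 scale at E14.5 than at E13.5, and condensate genes 0.61 higher. Foxd1 (3.61), Ptch1 (3.04), Cdkn1a (3.01), Sfrp5, a secreted Wnt antagonist (3.57), and Ly6a, a surface marker of the lower dermis (3.37), had large higher values. Pitx1, a hindlimb homeobox factor, had the lowest (-4.04). In the Shh line the step from E14.5 to E15.5 was 0.27 for Hedgehog targets and 0.35 for condensate genes, with Cldn10, a claudin, at 4.78 and Calb1 at -5.04. Extracellular matrix genes were higher at the later stage in both lines (0.68 and 0.63). In epithelium the differentiation list was higher by 3.65 and 1.57 and the cell cycle list was at -0.36 and -0.64.

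Stage cannot be separated here from other differences between libraries, since each stage of a line had 1 control library. Between the 3 control libraries at E14.5, the fibroblast median of condensate genes was -0.40 for the Shh over the β-catenin line, 0.22 for SmoM2 over β-catenin and 0.51 for SmoM2 over Shh, and that of Hedgehog targets was -0.21, 0.18 and 0.42. Clusters led by Nrgn and Calb1 held 747 and 760 of 4200 control fibroblasts of the Shh line at E14.5. They held 33 and 33 of 3418 in the β-catenin line and 73 and 19 of 3805 in the SmoM2 line. In the β-catenin control at E13.5 they held 601 and 667 of 4530. Calb1 and Cldn10 differed by up to 2.43 and 2.20 on the log2 scale between these E14.5 controls. Krtdap, a keratinocyte transcript, had the highest value in the β-catenin line's fibroblasts (3.63), where keratinocyte RNA was at 1.26. Malat1, a nuclear RNA, ranked first in the Shh line but was not read as a stage step: it was at 0.773 and 0.892 CPM in both E14.5 libraries of that line, whose reference has an added Malat1 entry, and at 8369.75 CPM in the E15.5 control. The median log2 ratio of all genes lay more than 0.1 from 0 in 3 of the stage steps, and the values above include it: -0.12 in epithelium of the β-catenin line, and -0.25 in epithelium and -0.15 in fibroblasts of the Shh line.

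**Figure D4:**
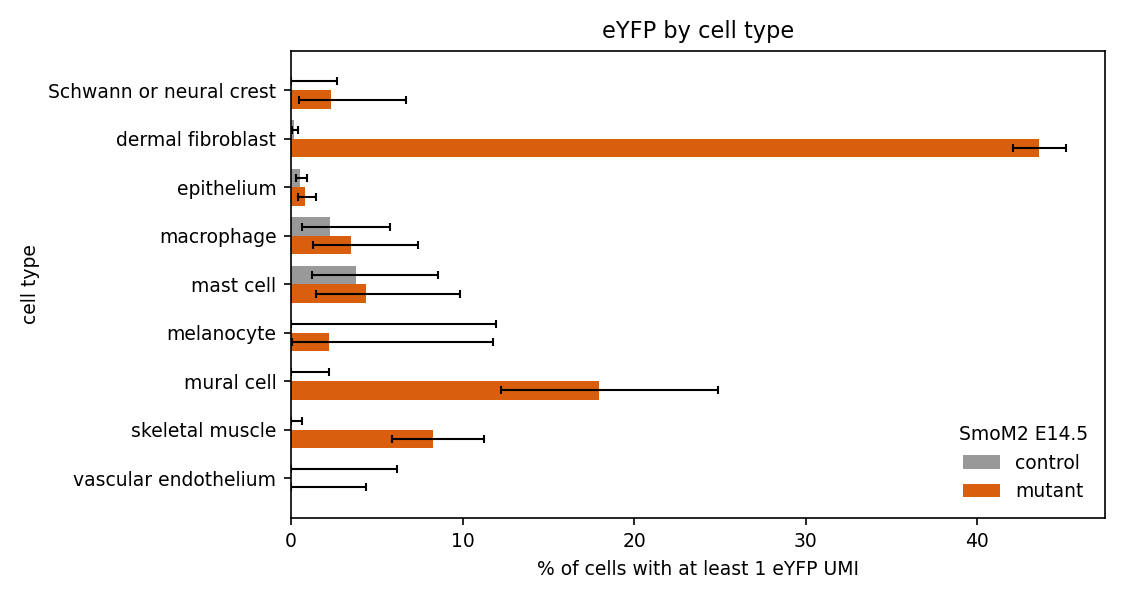
Percent of cells with at least 1 eYFP UMI in the SmoM2 pair, by cell type, for the control and the mutant library, with exact 95% binomial intervals. In the mutant library the share was 43.6% in fibroblasts, 17.9% in mural cells and 0.787% in epithelium.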

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

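The tests of dilution by suprabasal cells, of a capture or dissociation difference and of a smaller upper dermis were chosen after the results had been seen. The mural cell values and the gene-resampling interval of the rank correlations were also brought in afterwards.

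Lists with opposite directions at the 2 stages of a line drew attention, and none of these differences between stages was tested. In β-catenin epithelium, FGF response genes such as Dusp6 went from 0.30 at E13.5 to -1.07 at E14.5, a difference of -1.36. Erythroid RNA there went from -0.71 to 1.11, a difference of 1.82. In Shh epithelium the differentiation genes, Krt1 and Krt10 among them, went from 0.38 at E14.5 to -1.20 at E15.5, a difference of -1.58. Immediate early genes there went from 0.26 to -0.61, a difference of -0.864. Erythroid RNA in fibroblasts of the Shh line went from -1.60 to 0.30, a difference of 1.90.

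The added tdTomato entry of the Shh pair at E14.5, which no comparison used, had a signal above the limit of a count of 0: 17317 UMIs in the control library and 20019 in the library labelled Shh knockout. It was found in 49.9% of epithelial cells of the control library and 54.3% of those of the other, against 2.14% and 1.70% of fibroblasts. Whether it is a Cre reporter is not stated in the labels. The added GFP entry had 0 UMIs.

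Placode genes such as Dkk4 and Edar were lower in SmoM2 mutant epithelium (median -3.17). Dilution by suprabasal cells as the whole cause is argued against by the share of clusters with low Krt10. These held 87.9% of control and 83.5% of mutant epithelial cells, too close for a difference of this size. The median within them, -3.23 (-3.42 to -3.05), adds little. They hold most of the epithelium and both clusters led by placode genes, so it had to lie near that of the whole. A loss of placode cells in capture or dissociation cannot be told apart from their absence in the embryo. The clusters led by placode genes held 441 control and 2 mutant cells. The median in the others, -1.43 (-1.72 to -1.12), spans the halfway point to 0. It rests on the 5 members that reached the floor there (Bmp2, Wnt10a, Wnt10b, Dkk4 and Ltb), fewer than in the whole compartment. The medians thus cover different genes, and this comparison cannot decide. The handling response list was at 0.15 (percentile 96.5, inside the central 95%) with Egr1 at 2.06. SmoM2 made in most epithelial cells is argued against by an eYFP share of 0.787%, near the 0.534% of control epithelium and far from the 43.6% of fibroblasts. Whether this epithelium changed like β-catenin-deficient epithelium cannot be told apart from a weaker likeness. Across 3847 genes, which are not independent replicates, rho was 0.283 with the β-catenin pair at E14.5 and 0.188 with the Shh pair. The difference of 0.0950 (0.0456 to 0.142) spans the bound of 0.1 set beforehand. Values outside that test lay further toward likeness, with rho at 0.347 for β-catenin E13.5 and -0.0803 for Shh E15.5 and Pearson r at 0.285 and 0.109 for the E14.5 pairs. All rest on sums over the whole epithelium, so they do not separate changes within cells from shifts in cell share. The clusters led by placode genes held 34.9% of control and 2.59% of mutant epithelial cells at β-catenin E14.5, and 21.4% and 0.157% in the SmoM2 pair. They held 2.68% and 1.51% at β-catenin E13.5, 36.9% and 39.0% at Shh E14.5, and 18.6% and 46.0% at Shh E15.5.

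Hedgehog targets such as Ptch1 and Gli1 were lower in fibroblasts of the β-catenin mutant at E14.5 (median -2.42). A smaller share of upper dermis as the whole cause is argued against by the share of clusters with high Crabp1. These held 2382 of 3418 control and 3098 of 4831 mutant fibroblasts, too close for a difference of this size. The median within them, -2.72 (-2.82 to -2.57), could hardly have moved and adds little. They also include the condensate cluster, with 149 control and 3 mutant cells, so a loss of such cells is not separated. A loss of these transcripts throughout the library is argued against by a log2 ratio of -0.0184 (-0.26 to 0.22) of their summed counts outside epithelium and fibroblasts, against -2.63 in fibroblasts. That sum joins types that differed: mural cells, with 187 of its 339 mutant counts, were higher (0.41, with 0.065 to 0.76). Skeletal muscle was lower (-0.76, with -1.46 to -0.061), though by less than fibroblasts, and the intervals of the other types spanned 0. Whether the lack of detected Shh in this epithelium (0 UMIs) accounts for the pattern was not tested, which would need the β-catenin mutant with Shh restored.

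Hedgehog targets were higher in SmoM2 mutant fibroblasts (median 2.71). A library-wide difference as the whole cause is argued against by thinned cells: 86.5% of 1751 fibroblasts with an eYFP UMI had a target UMI and 63.0% of 2235 without one did, a difference of 23.5 points (median depth before thinning 18022 and 13200 UMIs), against 16.8% in the control library. Activation in fibroblasts alone passed the test set beforehand, with 0.45 (0.01 to 0.89) in macrophages, mast cells and endothelium, but that test left out types that carry eYFP, and it is argued against by mural cells (1.82, with 1.49 to 2.17). Fibroblast RNA in mural cells would bring its transcripts in 1 ratio, but mural cells held 14.01% (11.04 to 17.5) of the fibroblast level of Pdlim3, 4.40% (3.13 to 6.02) of Sox18 and 2.06% (1.18 to 3.35) of Dkk1. Foxd1 was at 6.28% (4.66 to 8.28), and Foxd2 at 13.1% (5.98 to 24.8) and Fgf5 at 3.63% (1.33 to 7.89) had wide intervals. For Hedgehog targets it was 16.2% (14.47 to 18.03), which includes the mural cells' own level, 31.6 CPM in control against 112 in the mutant library. Schwann or neural crest cells (2.44, with 1.04 to 4.17, from 5 and 27 counts) and melanocytes (1.93, with 0.17 to 4.32, from 3 and 20) were also higher, with eYFP shares of 2.34% and 2.22% beside 3.47% in macrophages, so which other types respond, and whether all of them carry the allele, stays open.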

How the results depend on the processing

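With 1 library per group these alternatives show dependence on processing alone, and the cause was not tested except where stated. All but the 2 choices of fibroblast clusters, added after the data had been seen, were planned. Median of ratios (14 results) and a resolution of 2.0 (19) left each result within its counting interval. With 5 CPM as pseudocount, β-catenin Wnt targets in epithelium were -1.27 at E13.5 and -0.88 at E14.5 and placode genes -1.43 at E14.5; Shh fibroblasts had Hedgehog targets at -1.36 (E14.5) and -1.39 (E15.5) and condensate genes at -0.43 and -0.92; SmoM2 fibroblasts had 2.46 and 0.77. The other 5 stayed within their intervals. Without a floor, β-catenin epithelium had Wnt targets at -0.26 and -0.83 and E13.5 placode genes at -0.51, and condensate genes were -1.22 (Shh E15.5) and 0.84 (SmoM2), with 9 unmoved. With doublets kept, β-catenin Wnt targets were -1.26 and -0.86 and E14.5 placode genes -2.69, with 16 unmoved. Under the stricter filter, β-catenin epithelium had Wnt targets at -1.26 and -0.72 and placode genes at -0.63 and -2.58. Those medians rest on 279 of 1718 control and 171 of 1456 mutant epithelial cells at E13.5. At E14.5 they rest on 970 of 2586 and 393 of 1547. This filter gave 2.62 for SmoM2 Hedgehog targets, and shares of -2.58 (β-catenin E14.5), -3.61 (Shh E15.5) and 5.87 (SmoM2) points. E13.5 fibroblast Wnt targets changed sign (0.0299), and 10 were unmoved. Equal weight per cell gave -1.28 and -3.08 for E14.5 β-catenin Wnt targets and placode genes, and condensate genes of -1.34 (β-catenin E14.5), -1.26 (Shh E15.5) and 1.18 (SmoM2), with 9 unmoved. At 2000 UMIs the share differences were -3.12 (β-catenin E14.5), -3.43 (Shh E15.5) and 5.55 (SmoM2), with at least 3 genes -0.510 (β-catenin E13.5), -2.38 (Shh E14.5) and 24.2 (SmoM2), and with at least 5 genes -1.23 (Shh E14.5), -3.61 (Shh E15.5) and 3.85 (SmoM2), with 2 unmoved each. The E13.5 share difference (-0.0317) changed sign within its counting interval at 2000 UMIs (0.0418) and with at least 5 genes (0.0124). In clusters with high Crabp1, signs turned for E13.5 β-catenin fibroblast Wnt targets (0.0446) and for SmoM2 Hedgehog targets (-1.07), condensate genes (-1.30) and share (-4.02 points), where the cluster of mostly mutant cells is left out by construction. Condensate genes there were -2.18 (β-catenin E14.5) and -1.66 (Shh E14.5), Shh Hedgehog targets -2.85 and -2.55, and shares -5.57 (β-catenin E14.5) and -2.85 (Shh E14.5), with 5 unmoved. Without the fibroblast cluster led by Scx and Tnmd, E13.5 β-catenin Wnt targets changed sign (0.00880), and 14 stayed within their counting intervals. Among these 14, the E13.5 share difference changed sign as well (0.0354). Pseudocount, floor, equal weight and median of ratios give no value for shares, and thinning and gene number none for medians. The E13.5 shares rest on 10 and 11 cells.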

Other observations

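The values in these paragraphs were chosen for mention after they had been seen. In the SmoM2 mutant library, mural cells, the contractile cells around vessels, carried eYFP in 17.9% (12.3 to 24.9) of 156 cells, and their Hedgehog targets summed to 112 CPM against 31.6 in control. Skeletal muscle carried it in 8.30% (5.91 to 11.3) of 446 cells, with 16.7 CPM against 6.76. Macrophages had an eYFP share of 3.47% in the mutant and 2.30% in the control library, and endothelium had 0 of 82 cells. Fibroblasts with an eYFP UMI had at least 4 of the 14 condensate genes in 13.99% of cells and those without one in 17.3%. Of them 98.3% and 69.6% lay in the cluster of mostly mutant cells.

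Casz1 and Irx3, transcription factors of dermal fibroblasts, were higher in both libraries labelled Shh knockout (0.57 and 1.62 for Casz1, 0.45 and 1.21 for Irx3) and lower in the SmoM2 mutant (-3.57 and -3.17). In epithelium, Cdh4 and Kcne1l, a potassium channel subunit, were higher in the β-catenin mutants (2.57 and 2.72, 2.53 and 2.78) and in the SmoM2 mutant (3.09 and 2.62). Of the 2 clusters led by placode genes, that of Dkk4, Krt17 and Ltb held 230 cells of the β-catenin control library at E14.5 and 10 of the mutant, 196 and 354 in the Shh line at E14.5, 207 and 489 at E15.5, and 231 and 0 in the SmoM2 pair. That of Dkk4, Krt17 and Kremen2 held 673 and 30, 934 and 890, 171 and 234, and 210 and 2 in the same order. Together they held 36.9% of control epithelial cells and 38.97% of those of the library labelled Shh knockout at E14.5, and 18.6% and 46.0% at E15.5.

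Across 4496 genes in fibroblasts, the log2 ratios of the β-catenin pair at E14.5 and of the SmoM2 pair had a Spearman rho of -0.473, and those of the Shh pairs with the SmoM2 pair -0.0527 at E14.5 and -0.151 at E15.5. The rho between both Shh pairs was 0.49998 and that between both β-catenin pairs 0.333. In epithelium the β-catenin pairs had 0.583. These are relations across genes, which are not independent replicates, and 10 were computed per compartment.

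The libraries of the Shh line at E15.5 kept the smallest shares of barcodes, 59.3% in control and 58.6% in mutant. Among E14.5 control libraries, immediate early genes, which respond to tissue handling, were lower in epithelium of the Shh line (-1.18) and of the SmoM2 line (-0.94) than in that of the β-catenin line.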
